A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

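Anti-FLAG ChIP-seq was compared between 3 WT and 3 rpd3Δ samples of Saccharomyces cerevisiae, a budding yeast. Per the labels' protocols, cultures of about 100 mL were grown at 23 °C, arrested in G1 with about 5 nM α-factor for about 4 h and cross-linked with 1% formaldehyde. Per the submitters' processing notes, Bowtie2, SAMtools and bedtools were used with the R64 build; versions, read filters, duplicate removal and the treatment of reads with several matches are not given in the sources used here. The deposited values are whole-number counts per 50 bp bin, 241434 bins on 16 nuclear chromosomes per sample, in the layout of a bedtools coverage table, with no normalization. A read that crosses a bin border is counted in each bin it touches, so that summed counts exceed the number of reads. No input library, mitochondrial DNA or 2-micron plasmid was analysed here, so signal cannot be set against unprecipitated DNA.

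Binding regions were called once on the sum of the 6 samples, without regard to genotype: bins smoothed over 500 bp at 2 or more times the median of the surrounding 20 kb, over at least 200 bp, where that median was at least 0.25 of the genome median, leaving out the rDNA and the deleted and marker genes. Background along chromosomes was the mean of bins outside the rDNA with a smoothed signal close to their local median, divided by that of the chromosomes other than XII. Gene positions came from the RefSeq gene table of the same build, with strand read from the locus tags. Promoters were the 500 bp upstream of the start codon. Counts were summed per window, windows with a mean under 10 counts were left out, and scaled counts per bin are counts divided by the effective library size and multiplied by its mean. Library size was set by TMM over 1192 complete bins of 10 kb outside the rDNA and the deleted genes, called background bins here. Binding regions, with 17.3% to 23.2% of the signal outside the rDNA per sample, were left in these bins. Scaling on the regions alone was not used, because it would remove a difference that all of them share. rpd3Δ was compared with WT by edgeR 4.0.16 (glmQLFit and glmQLFTest in R 4.3.3) with no covariate and Benjamini-Hochberg adjustment at 0.05 within each kind of window. Standard errors are the absolute log2 fold change over the square root of the quasi-likelihood F. Gene lists and origin groups were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted within each family of lists. Single values per sample were compared by an exact permutation test (both sides counted). DESeq2 1.42.0 was the alternative test. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

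Some steps differ from the plan made before the data were examined. The gene table gives no origins, so the 500 bp origin windows were replaced by whole intergenic intervals: 12 origins and the recombination enhancer were placed, from general knowledge, between named neighbouring genes after the files had been opened and before the values of these intervals were tested, and were tested among all intergenic intervals. An interval can hold more than the origin, and its length ran from 174 bp (ARS608) to 3805 bp (ARS609). ARS1511, ARS522 and the other planned origins were not analysed here. Position groups were formed from binding regions in place of origins, and origin groups were tested against intergenic windows in place of promoters. Ty and LTR sequence stayed in, since its positions were not used here. The overlap of gene list promoters with binding regions was added after the data were seen.

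Items were named by a rule fixed before the data were examined: the 10 regions with the highest peak over local signal; up to 10 rising and 10 falling regions, promoters and origins with the largest fold change among those past the threshold whose WT and rpd3Δ samples did not overlap; from each list up to 4 members past the threshold or, with 0 passing, the 2 with the highest signal; and always RPD3, FKH1, BAR1, CLB2, SWI5, ARS305, ARS607, ARS603 and the recombination enhancer. The 10 highest regions over 20 kb from chromosome ends and the other origins, members and regions named were chosen after their values were seen. Regions are named by the nearest gene.

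WT samples 1 and 2 were close, so all pairs were compared over the background bins by a chi-square divided by a factor for reads counted in neighbouring bins, estimated from the short-range covariance (2.46 for this pair). The chi-square per degree of freedom was 1.25 for WT samples 1 and 2 (p = 7.90e-09), 2.36 for 1 and 3, 3.34 for 2 and 3, and 1.39 for rpd3Δ samples 2 and 3. The rDNA shares of WT samples 1 and 2, 42.4% and 36.3%, also differed beyond counting error, so they were counted as 2 samples; a fit with both pooled as 1 is among the alternatives.

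The tests were checked on simulated counts with 50 windows changed by each of 4 known amounts. At a log2 change of 1 the test recovered 98% of changed windows for the 907 regions, 92% for the 5969 promoters and 88% for 5077 intergenic windows; at 0.7 it recovered 84%, 68% and 70%. The share of false calls was 3.54%, 5.26% and 4.28%. The simulation drew each window independently, with no quality difference shared by the windows of a sample. In the data the estimated correlation was 0.68 for regions near chromosome ends, so these shares need not hold for the real samples. Alternatives covered the scaling, the test, the low filter, region and window sizes, a replicate block and leaving out each sample. A local background offset, a signal-dependent scaling, the ratio of NTS2 to RDN25 as a covariate, the pooled WT samples, the window scaling with the block, and regions outside chromosome XII were added after the data were seen.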

Results

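The series title names the histone deacetylase Rpd3, single-copy replication origins, the ribosomal DNA (rDNA) array and the forkhead protein Fkh1, so the question addressed was whether binding of a FLAG-tagged protein changes along budding yeast chromosomes when RPD3 is absent. The labels do not name the tagged protein. Chromatin immunoprecipitation with an anti-FLAG antibody was sequenced from 3 WT and 3 rpd3Δ samples, all held in G1 with the mating pheromone α-factor, which keeps cells from entering S phase. Nothing in the labels says that the 3 samples of a genotype came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The summed bin counts were 4676274, 5907739 and 3987250 in the WT samples and 6250775, 6785491 and 4888453 in the rpd3Δ samples. Outside the rDNA they were 2649260, 3713744 and 2004858 in WT and 2748464, 2443077 and 1856558 in rpd3Δ. The medians there were 7 to 12 counts per 50 bp bin.

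The deleted genes were read first, because they check the labels. RPD3 (YNL330C, chromosome XIV, 18001 to 19302, R64) had a signal of 0.854 ± 0.0956 times the mean outside the rDNA in WT (SD, n = 3) and 0.0983 ± 0.0214 in rpd3Δ. BAR1 (YIL015W, chromosome IX, 322342 to 324105), which encodes a protease that degrades α-factor, had 0 counts in all 6 samples. FKH1 (YIL131C, chromosome IX, 100781 to 102235) had 0.775 ± 0.0442 in WT and 0.862 ± 0.144 in rpd3Δ.

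The rDNA, the tandem repeat of ribosomal RNA genes on the right arm of chromosome XII, held a large part of all signal in both genotypes. Its share was 42.4% ± 6.05 in WT and 59.2% ± 3.93 in rpd3Δ (SD, n = 3), with every rpd3Δ sample above every WT sample. The exact permutation p, both sides counted, was 0.1, the smallest that 3 samples against 3 can give. RDN25, the 25S rRNA gene, had 393.0 ± 233 times the mean outside the rDNA in WT and 1036 ± 396 in rpd3Δ (exact permutation p = 0.2), and RDN18, the 18S gene, had 405 ± 158 and 918 ± 226 (exact permutation p = 0.1). NTS1, the fork barrier spacer, had 606 ± 75.1 and 939.9 ± 112 (exact permutation p = 0.1). NTS2, the spacer with the origin, had 1101 ± 269 and 1398 ± 468 (exact permutation p = 0.5). The third WT sample stood apart from the other WT samples, with 661 over RDN25 against 286 and 232. The first rpd3Δ sample stood apart from the other rpd3Δ samples, with 579 against 1256 and 1274, so the genotypes overlapped over RDN25. The ratio of NTS2 to RDN25 was 4.90, 4.36 and 1.34 in the WT samples and 3.25, 1.09 and 0.744 in the rpd3Δ samples.

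**Figure D1:**
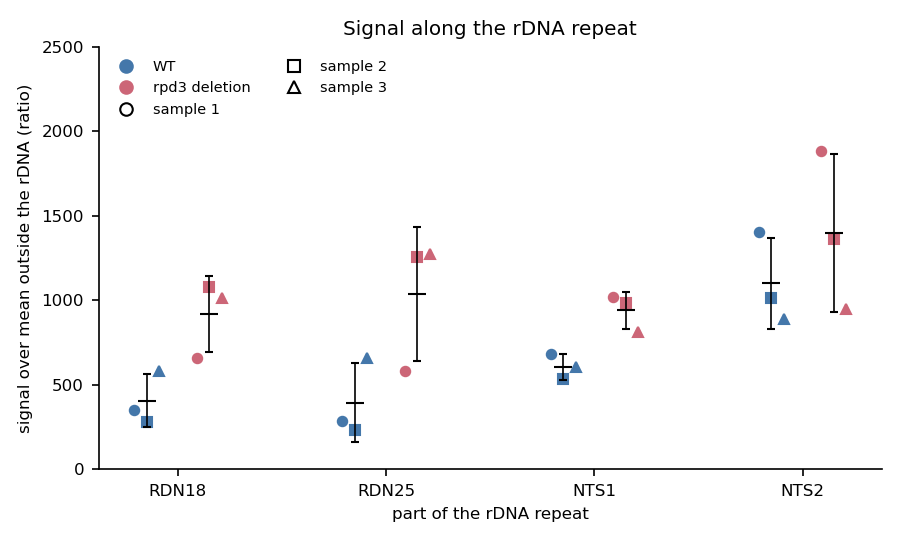
Signal over 4 parts of the rDNA repeat, as a ratio to the mean outside the rDNA, for each sample (blue, WT; red, rpd3Δ; the symbol gives the sample number), with the mean and SD as black bars (n = 3). RDN25 averages 393.0 in WT and 1036 in rpd3Δ, and NTS2 averages 1101 and 1398, both with overlapping samples.

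Between binding regions the signal was uneven along chromosomes in every sample, given here relative to the mean of the chromosomes other than XII. On chromosome XII it was high on both sides of the rDNA. From 20 to 50 kb to the right it was 1.598 ± 0.0615 in WT and 2.25 ± 0.134 in rpd3Δ (SD, n = 3), and from 5 to 50 kb to the left 1.43 ± 0.0635 and 1.92 ± 0.0389. The left arm of chromosome XII had 0.849 ± 0.00540 and 0.824 ± 0.0307. From 5 to 20 kb of the ends of the other chromosomes it was 0.987 ± 0.00187 in WT and 0.835 ± 0.00809 in rpd3Δ, a log2 ratio of -0.24. Within 20 kb of their centromeres it was 0.843 ± 0.0112 and 0.804 ± 0.0244. Across the 30 arms outside chromosome XII, which are not independent replicates, background and arm length had a Spearman rho of 0.903 to 0.947 and a Pearson r of 0.838 to 0.902 per sample. These differences were not tested.

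**Figure D2:**
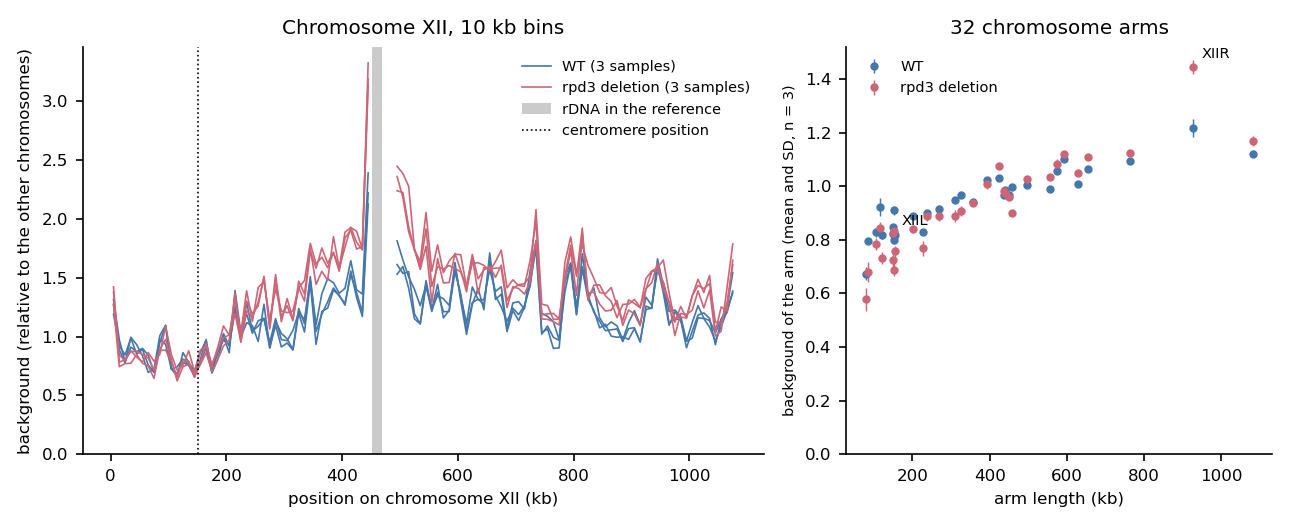
Background between binding regions along chromosome XII in 10 kb bins, 1 line per sample (left), and the mean and SD (n = 3) for each of 32 chromosome arms against arm length in kb (right), relative to the other chromosomes (blue, WT; red, rpd3Δ). The right arm of chromosome XII has 1.22 in WT and 1.45 in rpd3Δ.

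Outside the rDNA, 907 binding regions were called that covered 766 kb in total, with a median length of 700 bp. They held 21.6% ± 2.11 of the signal outside the rDNA in WT and 19.5% ± 2.63 in rpd3Δ (SD, n = 3). Most of that signal thus lay between them. Of the 907 regions, 372 lay in promoters, 267 in other intergenic sequence, 220 in coding genes and 48 at tRNA genes. The region with the highest peak over its surroundings was the last 533 bp of the right end of chromosome XIV (beside YNR077C), and 9 of the 10 highest lay at chromosome ends, which share repeated X and Y′ sequence, so that their reads cannot be assigned to 1 end with certainty. The exception was the region over RUF22 (chromosome VI, 198701 to 200300), which contains the interval of ARS607, with a peak of 33.4 times the local median. Over 20 kb from chromosome ends, the next highest were those beside TEM1, which encodes the GTPase of the mitotic exit network (chromosome XIII, 145401 to 147450, 24.1 times), YOL024W (chromosome XV, 277001 to 278500, 23.5 times), HOS3, which encodes another histone deacetylase (chromosome XVI, 328551 to 330000, 21.6 times), and YJR098C (chromosome X, 612351 to 613950, 20.5 times). The recombination enhancer between KAR4 and SPB1, a known Fkh1 site, gave a region with a peak of 16.7 times the local median. The mean signal of all regions over the sequence between them was 4.06 ± 0.499 in WT and 3.57 ± 0.604 in rpd3Δ (SD, n = 3, exact permutation p = 0.2).

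Between genotypes, 39 regions were lower and 11 higher in rpd3Δ by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. The largest decrease was beside FLO1, a flocculin gene (chromosome I, 211051 to 212000), from 23.7 ± 3.89 to 5.57 ± 0.471 scaled counts per bin (SD, n = 3 each), a log2 fold change of -2.09 (SE 0.189, edgeR adjusted p = 6.83e-06). The regions beside YAL064W (chromosome I, 20251 to 21050, log2 fold change -2.01) and FLO5 (chromosome VIII, 531401 to 532400, -1.69) were lower as well. FLO1 and FLO5 are paralogs in duplicated subtelomeric sequence, and YAL064W lies beside FLO9, a further paralog, so these values are uncertain as to copy. Single sites that fell lay beside SUT418 (chromosome XVI, 588451 to 589000, -1.64), over YGL118C (chromosome VII, 287601 to 288450, -1.19), over PRR2 (chromosome IV, 73851 to 74950, -0.996) and beside MNT4 (chromosome XIV, 736551 to 737000, -0.97). YCL074W, a pseudogene fragment of a Ty element on the left end of chromosome III (3801 to 4400), fell by 1.36 on the log2 scale. RUF22, which overlaps the ARS607 interval, fell from 127 ± 26.2 to 63.1 ± 19.2 scaled counts per bin (log2 fold change -1.01, SE 0.217, edgeR adjusted p = 0.0157). The region beside YCL049C (chromosome III, 38901 to 40050), which overlaps that of ARS305, fell from 43.1 ± 8.29 to 21.9 ± 5.36 (-0.98, SE 0.208, edgeR adjusted p = 0.0157).

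Among the regions that rose, BPT1, which encodes a vacuolar transporter, had the largest change (chromosome XII, 119251 to 119650), from 8.95 ± 1.503 to 22.0 ± 4.71 scaled counts per bin (log2 fold change 1.32, SE 0.214, edgeR adjusted p = 0.00165). A pair of regions near the acid phosphatase genes PHO5 and PHO3 rose, by log2 fold changes of 1.18 (chromosome II, 430701 to 431250) and 0.88 (429001 to 429550). These genes are closely related neighbours, so their values are uncertain as to copy where their sequence is shared. The region upstream of DIN7, a mitochondrial nuclease gene (chromosome IV, 995301 to 996200), rose from 30.7 ± 6.53 to 68.8 ± 17.3 (log2 fold change 1.16). Smaller rises were measured at the tRNA gene YNCO0021C (0.81), SEY1 (0.79), the zinc transporter gene ZRT1 (0.76), SKY1 (0.74), IMD4 (0.72) and SHM2 (0.65).

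By peak height, 55 of the 58 regions with a peak over 10 times the local median had a negative fold change (median -0.43), 32 of them near chromosome ends. By position, 82 of the 90 regions within 20 kb of a chromosome end had a negative fold change, with a median of -0.42 against -0.08 for the other 817 regions. With a peak under 10 times the local median, the medians were -0.39 for 58 regions near ends and -0.07 for 791 elsewhere, and with a higher peak the 26 regions away from ends had -0.27. Of the 90 regions, 16 passed the test as lower and 0 as higher by edgeR. The set test (camera) gave an adjusted p of 2.44e-12 with a preset correlation and an adjusted p = 0.781 with an estimated correlation, so the call was lost. The 56 regions within 20 kb of a centromere had a median of -0.20 (camera adjusted p = 0.188) and the 48 regions at tRNA genes one of -0.10 (camera adjusted p = 0.969). The median of all regions was -0.10. The 82 regions of chromosome XII had a median of 0.13, of which 3 passed as higher and 0 as lower, while 4 each passed as lower on chromosomes I, III, VI and VIII. The background differed in the same directions, with a log2 ratio of rpd3Δ to WT of 0.25 on the right arm of chromosome XII and -0.24 near chromosome ends. On the left arm of chromosome XII, which holds BPT1, that ratio was -0.04. Of the 3 that passed on chromosome XII, BPT1 had 1.43 ± 0.239 times the local background in WT and 3.73 ± 1.08 in rpd3Δ, SHM2 2.72 ± 0.277 and 3.52 ± 0.145, and the ribosomal protein gene RPS31 (499151 to 499750) 2.59 ± 0.475 and 2.75 ± 0.323.

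The balance of higher and lower regions depended on scaling: scaling on the regions themselves gave 114 higher and 141 lower, total signal gave 1 and 346 with a median of -0.61 over all regions, and the ratio of NTS2 to RDN25 as a covariate gave 175 and 103. The local background of each sample as an offset left 4 higher and 6 lower, all among the 50 calls. Without either the first or the second WT sample 3 rose and 7 fell, without the second rpd3Δ sample 2 and 6, and only FLO1, YAL064W, FLO5, SUT418, YCL074W and YGL118C as lower and BPT1 and the PHO5 site at 430701 as higher passed whichever sample was left out.

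**Figure D3:**
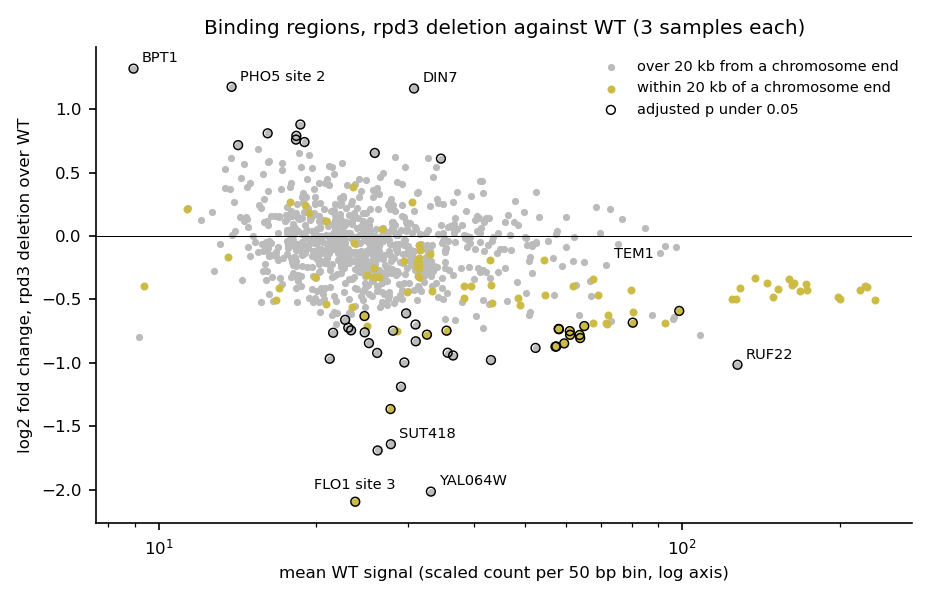
Log2 fold change (rpd3Δ over WT, n = 3 each) of the 907 binding regions against their mean WT signal in scaled counts per 50 bp bin on a log axis; yellow points lie within 20 kb of a chromosome end and rings mark an edgeR adjusted p under 0.05. The median of the 90 regions near ends is -0.42, and the lowest point, beside FLO1, is at -2.09.

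Origins were compared over the intergenic intervals that hold 12 named origins of chromosomes III, IV and VI. In rpd3Δ signal fell at 5 of them and rose at 0 by edgeR. DESeq2 also called 0 as higher, and 0 of the 12 were higher at an unadjusted p under 0.05. ARS607, an early-firing origin between ROG3 and PES4 (chromosome VI, 199035 to 199873), had the highest signal, 219 ± 47.3 scaled counts per bin in WT and 105 ± 34.7 in rpd3Δ (log2 fold change -1.06, SE 0.226, edgeR adjusted p = 0.00658). ARS305, between APA1 and YCL049C (chromosome III, 38802 to 39785), went from 45.7 ± 8.58 to 23.4 ± 6.34 (-0.96, SE 0.186, edgeR adjusted p = 0.00305), and ARS306, between HBN1 and FRM2 (73987 to 74703), from 47.3 ± 11.2 to 24.5 ± 6.27 (-0.94, SE 0.183, edgeR adjusted p = 0.00305). ARS606, between SUP11 and DCV1 (chromosome VI, 167526 to 167887), fell by 0.74 on the log2 scale and ARS319, beside the right end of chromosome III (314982 to 315996), by 0.66. ARS319 belongs to the late or inactive list. Near the end where it lies, reads in repeated sequence cannot be assigned to 1 end with certainty, and regions within 20 kb of ends had a median of -0.42. At all 5 of these origins each rpd3Δ sample lay below each WT sample. At ARS319 this held only just, with 46.6 scaled counts per bin in rpd3Δ sample 1 against 46.8 in WT sample 3. Chance separates 3 samples from 3, in either direction, with a share of 0.1.

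The other early origins did not pass over all 5078 intergenic windows tested. ARS416, beside TRP1, had a log2 fold change of -0.47 (edgeR adjusted p = 0.133), and TRP1 itself, whose end abuts it, had 2.45 ± 0.343 times the mean signal in WT and 1.78 ± 0.279 in rpd3Δ. ARS307, ARS309 and ARS315 had -0.14, 0.19 and -0.20. Among the late or inactive origins, ARS603 had 4.18 ± 0.406 scaled counts per bin in WT and 5.95 ± 1.66 in rpd3Δ (log2 fold change 0.52, edgeR adjusted p = 0.388), at or near background in both, and ARS608 and ARS609 had 0.02 and -0.36. The recombination enhancer (chromosome III, 28937 to 31448) had 38.1 ± 5.57 and 37.7 ± 7.84, a log2 fold change of -0.01 with an SE of 0.201.

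Adjusted over the list alone, 6 of the 12 origins were lower, the added one being ARS416. As a group, the 8 early origins had a median log2 fold change of -0.60 and the 4 late or inactive ones a median of -0.17; camera gave the early group an adjusted p of 9.58e-06 with the preset correlation and an adjusted p = 0.217 with an estimated correlation, and the late group an adjusted p of 0.291. The difference between the groups was not tested. In WT, ARS603, ARS608 and ARS609 had only 0.724, 1.602 and 1.22 times the local background, against 7.74 for ARS319, which fell. The early origins that passed had 5.47 to 32.1 times, and the other early ones 1.15 to 3.71. The 2 medians thus cannot tell firing time from signal level. Signal level alone did not set the change everywhere, since the recombination enhancer had 5.24 times and a log2 fold change of -0.01. Fewer than 5 origins passed in several settings: 0 without the first WT sample, the second WT sample or the second rpd3Δ sample, 0 with the local background of each sample as an offset, 2 with the first and second WT samples pooled, 3 with 1000 bp windows, and 4 without the third rpd3Δ sample. The median log2 fold change of ARS305, ARS306, ARS606, ARS607 and ARS319, -0.94 (median SE 0.186), was then -0.86 (0.223), -0.83 (0.218), -0.94 (0.246), -0.78 (0.214), -0.85 (0.217), -0.91 (0.201) and -0.77 (0.193) in that order.

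**Figure D4:**
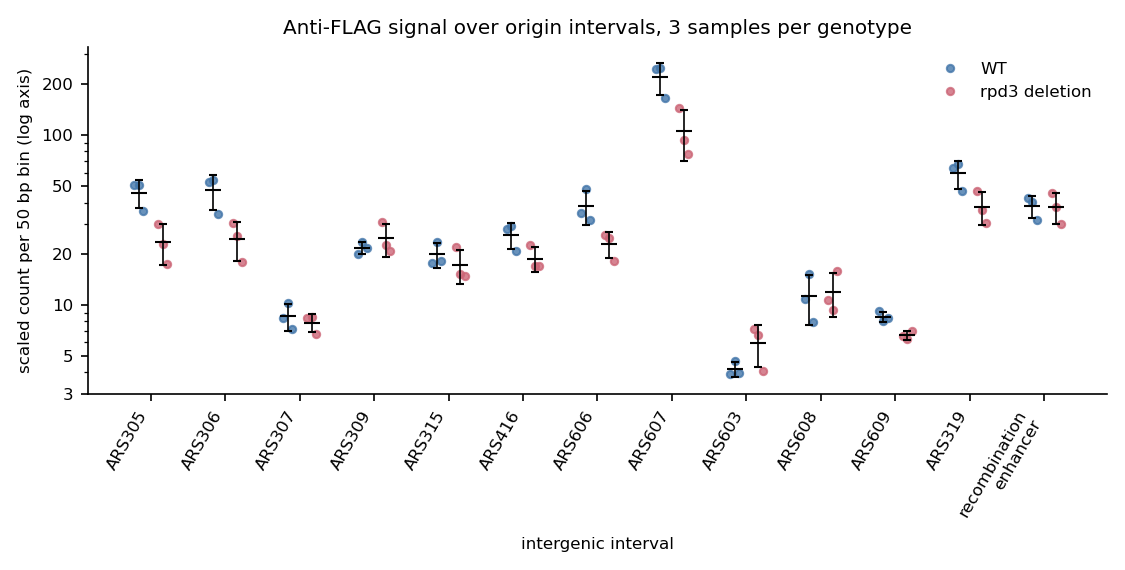
Signal over 12 origin intervals and the recombination enhancer in scaled counts per 50 bp bin on a log axis; dots are single samples (blue, WT; red, rpd3Δ), and black bars give the mean and SD (n = 3). At ARS305, ARS306, ARS606, ARS607 and, only just, ARS319 every rpd3Δ sample lies below every WT sample. At the recombination enhancer the means are 38.1 and 37.7.

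Of 5969 gene promoters tested (500 bp upstream of the start codon), 65 were lower and 17 higher in rpd3Δ by edgeR. PHO5 (chromosome II, 430952 to 431451) rose from 12.8 ± 0.970 to 28.4 ± 4.11 scaled counts per bin (SD, n = 3, log2 fold change 1.16, SE 0.190, edgeR adjusted p = 0.000103), and PHO3 (429102 to 429601) from 18.4 ± 1.40 to 34.9 ± 4.63 (0.92). DIN7 had the largest rise (1.19), and FPR4 (0.89), YDL218W (0.85), PCD1 (0.82), IDP2 (0.81), YOL057W (0.77), THI7 (0.76) and CSR1 (0.75) followed. FPR4, PCD1, IDP2, THI7 and CSR1 lie on the right arm of chromosome XII, the arm that carries the rDNA. Relative to the local background, FPR4 had 1.14 ± 0.272 in WT and 1.78 ± 0.177 in rpd3Δ, PCD1 1.003 ± 0.0480 and 1.25 ± 0.174, IDP2 1.17 ± 0.142 and 1.46 ± 0.171, THI7 1.65 ± 0.117 and 2.24 ± 0.0881, and CSR1 1.81 ± 0.359 and 2.57 ± 0.884. The largest decreases were at MDE1 (-1.31), PAU10 (-1.30), SNO2 (-1.19), YOL164W-A (-1.14), AUA1 (-1.04), DAN1 (-1.04), YAL064W (-0.996), MND2 (-0.98), ARO5 (-0.98) and IRC4 (-0.96). PAU10 and DAN1 belong to subtelomeric families of cell wall proteins with close paralogs, so their values are uncertain. MDE1 had 7.94 ± 1.78 scaled counts per bin in WT and 3.14 ± 1.31 in rpd3Δ, both below the local background. SNO2 (0.785 and 0.376 times the local background) and DAN1 (0.827 and 0.491) also lay below it in both genotypes. PAU10 (1.04 in WT and 0.521 in rpd3Δ) and MND2 (1.05 and 0.660) lay near it in WT. In WT, YOL164W-A had 1.37 times, IRC4 1.36, AUA1 1.45 and YAL064W 2.03. ARO5, whose window overlaps the region over YGL118C, went from 26.8 ± 4.64 to 13.6 ± 2.74 scaled counts, or 3.09 and 1.59 times the local background.

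Scaling on the promoters themselves gave 66 higher and 53 lower, total signal 1 and 3088, and the ratio of NTS2 to RDN25 as a covariate 124 and 65. The local background of each sample as an offset left 6 higher and 8 lower, with 11 of the 82 calls shared. DESeq2 gave 22 higher and 32 lower, with 34 of the 82 calls shared, windows of 1000 bp gave 104 and 256 with 76 shared, and windows of 300 bp gave 5 and 26 with 26 shared. Without the first WT sample 1 promoter rose and 13 fell, without the second WT sample 3 and 6, without the third rpd3Δ sample 34 and 46, and without the first rpd3Δ sample 21 and 147. PHO5 as higher and YAL064W, YOL164W-A and FRE7 as lower were the only promoters that passed whichever sample was left out, so that DIN7, MDE1 and the other promoters named here each lost the call without at least 1 sample.

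Gene lists fixed beforehand were compared at their promoters. In each of the 7 lists, 0 promoters passed as higher and 0 as lower over all genes by edgeR; DESeq2 called 1 of the G1/S list and 1 of the ribosomal protein list higher. In the CLB2 cluster, mitotic genes bound by Fkh1 or Fkh2, 13 of 21 promoters (61.9%) overlapped a binding region, against 15.6% of all promoters tested. Over the other lists the share ran from 20% (G1/S genes) to 86.7% (highly transcribed metabolic genes), and no untagged control was analysed here. DBF2 had 66.6 ± 13.6 scaled counts per bin in WT and 58.7 ± 14.5 in rpd3Δ, while CLB2 had 15.7 ± 3.65 and 18.6 ± 2.99 and SWI5 16.7 ± 3.57 and 16.5 ± 3.88. Their log2 fold changes were -0.18, 0.24 and -0.01. The list as a whole had a camera adjusted p of 0.592, 3 members were lower and 0 higher at an unadjusted p under 0.05, and 1 was lower adjusted over the list alone. The FKH1 promoter had 13.2 ± 2.35 and 12.8 ± 1.85.

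Of the 22 tested mating pheromone response genes, which α-factor induces, 19 had a negative fold change, with a median of -0.26. MFA2, an a-factor gene, had 66.3 ± 6.56 scaled counts per bin in WT and 62.0 ± 17.99 in rpd3Δ, and KAR5, needed for nuclear fusion, 56.7 ± 9.63 and 45.5 ± 15.2. The camera adjusted p was 0.0195 with the preset correlation, and an adjusted p = 0.563 with an estimated correlation ended the call. At an unadjusted p under 0.05, 6 members were lower and 1 higher, and 3 were lower adjusted over the list alone. Of the 8 histone genes, 7 had a negative fold change (median -0.28, camera adjusted p = 0.0796). HHF1 had 29.7 ± 4.32 and 20.6 ± 3.38 and HTA1 23.1 ± 2.37 and 22.8 ± 2.75. At an unadjusted p under 0.05, 3 histone genes were lower and 0 higher, and 3 were lower adjusted over the list alone. HHF1 and HHT1 share 1 promoter, and each is near-identical to a second copy.

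The 137 ribosomal protein genes divided almost evenly, with 72 positive and 65 negative fold changes and a median of 0.01. Against the other promoters camera gave an adjusted p of 0.0323 in the upward direction with the preset correlation, and an adjusted p = 0.563 with an estimated correlation. RPS1B, which shares its upstream region with TEM1, had the highest promoter signal of the list (143 ± 28.8 in WT and 116 ± 30.5 in rpd3Δ), and RPS22A had 89.0 ± 22.1 and 92.6 ± 21.1. In this list 7 members were higher and 4 lower at an unadjusted p under 0.05, and 0 passed in either direction adjusted over the list alone. Among 20 G1/S genes controlled by SBF or MBF, RNR1 had 34.0 ± 7.37 and 46.4 ± 12.5 and SWE1 24.9 ± 2.38 and 30.7 ± 7.34 (list median 0.09, camera adjusted p = 0.0956). In this list 1 member was higher and 1 lower at an unadjusted p under 0.05, and 1 was higher adjusted over the list alone. Among 13 genes repressed by Ume6 and Rpd3, CAR1 had 30.4 ± 4.05 and 29.5 ± 7.12 and ZIP1 26.0 ± 4.00 and 26.3 ± 5.11, where the list median was 0.01 (camera adjusted p = 0.215) and 0 members had an unadjusted p under 0.05 in either direction. Among 15 highly transcribed metabolic genes, PDC1 had 61.1 ± 8.17 and 74.2 ± 9.60 and ADH1 49.0 ± 8.597 and 43.3 ± 7.20, with a list median of -0.15 (camera adjusted p = 0.592) and 2 lower and 0 higher at an unadjusted p under 0.05. In the last 2 lists 0 members passed adjusted over the list alone.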

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

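The local offset, signal-dependent scaling, NTS2 to RDN25 covariate, pooled WT samples, window scaling with the block, and regions outside chromosome XII were chosen after seeing the data; unless stated, the cause of a change was not tested. Against 11 higher and 39 lower regions, 17 and 65 promoters and 5 lower origins, TMM over the tested windows gave 114, 141, 66 and 53 with 5 origins, DESeq2 size factors 115, 135, 65 and 53 with 5 origins, total signal 1, 346, 1 and 3088 with 9 origins, the DESeq2 Wald test 23, 73, 22 and 32 with 5 origins, the local 20 kb background offset 4, 6, 6 and 8 with 0 origins, signal-dependent scaling 67, 90, 78 and 83 with 5 origins, the NTS2 to RDN25 covariate 175, 103, 124 and 65 with 6 origins, and WT samples 1 and 2 pooled as 1 sample 3, 6, 3 and 19 with 2 origins. In total signal the rDNA enters the library size, which by construction lowers rpd3Δ elsewhere; the median log2 fold change was then -0.61 over regions and -0.57 over promoters, against -0.10 and -0.06 with background scaling. Regions at 3 times the local median gave 1 higher and 32 lower, 1000 bp promoters 104 and 256, 300 bp promoters 5 and 26, and 1000 bp origin windows 3 lower. Without 1 sample in turn, higher regions ranged from 2 to 20, lower regions from 6 to 181, higher promoters from 1 to 34, lower promoters from 6 to 147 and lower origins from 0 to 6, and leaving out 1 sample also leaves fewer degrees of freedom. The rDNA share ratio of rpd3Δ to WT was 1.40 and ranged from 1.30 to 1.503, and against the median bin the ratio was 1.97; the region enrichment ratio ranged from 0.796 to 0.941. With an estimated correlation the adjusted p was 0.563 for mating and ribosomal protein genes, 0.217 for early and all placed origins and 0.781 for regions near chromosome ends. Without 1 sample the adjusted p ranged from 0.000398 to 0.189 for mating genes, 0.00997 to 0.139 for ribosomal protein genes, 1.74e-12 to 0.00099 for early origins, 3.66e-11 to 0.00228 for all placed origins and 4.66e-13 to 9.13e-11 for regions near ends. The YCL075W region reversed to 0.13 with the local offset, and with the covariate HOS3, SKN1 and KAR4 turned positive, at 0.21, 0.28 and 0.27. Whether replicate numbers pair the samples stays open. Deviations of same-numbered samples correlated at 0.26, -0.04 and 0.33. The same-numbered rpd3Δ sample was the best match of WT samples 1 and 3, but WT sample 2 correlated best with rpd3Δ sample 1 (0.25). The replicate block gave 45 higher and 158 lower regions, 53 and 137 promoters and 6 lower origins, and with TMM over the windows 133 and 166, 103 and 90, and 6. With no low filter the counts were 11, 39, 17 and 65 with 5 origins, regions of at least 500 bp gave 8 higher and 29 lower, and regions outside chromosome XII 8 and 41. Among the alternative values of single named items and of the other lists, 1407 stayed on the same side of the threshold. A change of sign between fits that both missed the threshold was counted among these. Of the rest, 187 were weaker, 116 stronger and 4 reversed. Depth, with medians of 7 to 12 counts per bin, limits short windows. Changes of 0.7 on the log2 scale were recovered in 68% to 84% of simulated cases, which left out correlation between windows.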

Other observations

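The tests of explanations below were all chosen after the results were seen. Promoters of the lists fixed beforehand overlapped binding regions to very different extents. Of 15 highly transcribed metabolic genes 13 overlapped one (86.7%, Fisher's exact test against all other promoters, adjusted p = 1.603e-08), as did 13 of 21 CLB2 cluster genes (61.9%, adjusted p = 6.18e-06), 13 of 22 mating pheromone response genes (59.1%, adjusted p = 8.64e-06) and 4 of 8 histone genes (adjusted p = 0.0340). The share was 23.4% for 137 ribosomal protein genes (adjusted p = 0.0288), 23.1% for 13 genes repressed by Ume6 and Rpd3 (adjusted p = 0.514) and 4 of 20 for G1/S genes (adjusted p = 0.539), against 15.6% of all promoters. The promoters of RPS22A (10.7 times the local background in WT), PDC1 (6.78), MFA2 (6.75), ADH1 (6.55) and TDH3 (4.64) were among the most occupied of their lists, as were those of the CLB2 cluster genes DBF2 (7.94), BUD3 (5.52) and BUD4 (4.46). Genes and promoters are not independent replicates, and no untagged control was analysed here.

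The background between binding regions was high on chromosome XII around the rDNA and low near centromeres. Cells in S phase would raise sequence near the early-replicating centromeres, but the highest of the 6 samples had 0.856 there, below the mean. Background followed arm length in every sample and no input was analysed, so this level cannot exclude a small rise from S-phase cells. An extra copy of chromosome XII could raise the whole chromosome; in the data its left arm was at most 1.14 times the median of 9 other short arms, above the bound of 1.1 in the 3 rpd3Δ samples and in 0 WT samples, so a small excess in rpd3Δ stays open, but the rise toward the rDNA was at least 1.16 times that over the same centromere distances on other arms in all 6 samples, which a uniform extra copy would not give. A candidate explanation is proximity to the rDNA in the nucleus, where the strongest signal lies: the background fell with distance to the right of the rDNA in all 6 samples, with a Spearman rho of -0.356 or lower over 59 bins of 10 kb. This is a hypothesis found and tested on the same data, and a biological effect of RPD3 on nuclear position was not tested.

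The rDNA share was higher in each rpd3Δ sample than in each WT sample, with an exact permutation p of 0.1. More rDNA copies in rpd3Δ would raise NTS2 and RDN25 alike; their ratio had an exact permutation p of 0.2 between genotypes, and with 3 samples each and WT ratios of 1.34 to 4.90 this cannot be told apart from no difference. A difference in library quality of the kind that separates samples of 1 genotype stays open: the largest factor between WT samples was 2.85 for RDN25 and 1.58 for NTS2, against 2.64 and 1.27 between the genotype means, but 1.33 against 1.40 for the rDNA share, 1.67 against 1.995 for the whole rDNA over the mean outside it, 2.07 against 2.27 for RDN18 and 1.28 against 1.55 for NTS1. The RDN25 factor between WT samples rests on sample 3, with 661 against 286 and 232 in samples 1 and 2. Copy number was not measured apart from the immunoprecipitate, and an effect of RPD3 on binding in the rDNA stays open as untested.

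For the lower signal at origins and regions, chance was examined over the 10 splits of the 6 samples into 3 and 3, too few for a share under 0.05. The real split called 50 regions and the highest other 160 (2 splits with as many), 82 promoters against 0 (1 split), and 5 origins against 0 (1 split); the split with 160 set WT samples 1 and 2 and rpd3Δ sample 1, those with the highest region enrichment, against the rest, which points to a structure of the samples. Weaker enrichment in the rpd3Δ immunoprecipitates stays open for regions. Of 58 with a peak over 10 times the local median, 55 were negative (median -0.43), but many of these lie near chromosome ends. Away from ends 23 of 26 were negative, with a median of -0.27. With the NTS2 to RDN25 ratio as a covariate 37.1% of called regions were lower. Lower calls then went from 39 to 103 and higher calls from 11 to 175 with all 50 calls kept, so that share decides nothing. Weaker enrichment stays open at ARS305, ARS306, ARS606, ARS607 and ARS319 too, which were picked because they passed. A lower regional background stays open there as well, as a part of the fall or the whole. Their median log2 fold change went from -0.94 (median SE 0.186) to -0.57 (0.110) with the covariate, all 5 passing. With the local offset it was -0.78 (0.214), and 0 passed. Over all 12 placed origins the median went from -0.42 (0.185) to -0.28 (0.128) with the covariate and -0.26 (0.211) with the offset. Background on the arms that hold the 5 had log2 ratios of -0.13 (III left), -0.08 (III right) and -0.16 (VI right), and -0.24 from 5 to 20 kb of chromosome ends. These background ratios are smaller in size than the fall at the 5. Those 5 were picked on the same data, however, and over all 12 the offset left -0.26 (0.211) with 0 passing. The values thus cannot decide whether regional background makes up the whole of the fall at the 5. An effect of RPD3 on binding at these origins stays open as a hypothesis, resting on the samples named in the report.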
